A study of Mus musculus with 12 samples.

How the data were processed

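RNA from the left ventricle of mice was measured by RNA sequencing in 12 libraries, 3 for each of 4 groups: wild type after sham surgery, wild type after transverse aortic constriction (TAC), Prkca T497A after sham surgery and Prkca T497A after TAC. Per the labels' protocols, surgery was done at 10 weeks of age with a 27-gauge needle, tissue was taken 5 weeks later, total RNA was extracted with a column kit, libraries were made with an mRNA HyperPrep kit and sequenced single-end for 75 cycles. The labels name the cell type as cardiomyocyte and the tissue as left ventricle, and the protocol describes extraction from cardiac tissue with no sorting step. Groups were taken from the sample labels. All titles carry the same replicate number, so replicates were numbered in accession order and a shared number pairs no libraries. The labels give 1 batch date for all 12 libraries. Each title also carries a number of its own, high in all T497A TAC libraries and low in most others. The labels do not state what this number stands for. They do not state that each library is a separate animal, so p-values measure the spread between these libraries.

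The deposited table holds whole-number read counts for 55401 genes, not normalized. Per the submitters' processing notes, the tools named are Trim Galore 0.6.4, STAR 2.7.3a, featureCounts, Subread 1.6.3 and limma 3.50.3, with the mm10 build; their order, settings, annotation release and use of strand are not given in the sources used here. How reads that map to several places were counted is also not given, so counts of processed pseudogenes and of genes with near-identical copies are uncertain, as are those of genes that overlap on opposite strands. Gene positions were taken from a GENCODE annotation of GRCm38, to which 15751 of the 15764 tested genes matched by identifier. A total of 217 genes carry a symbol that another gene also carries.

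Totals ran from 36862004 to 46898344 counts per library, and the biological coefficient of variation was 17.2%. Replicates of each group were compared before averaging; the chi-square per degree of freedom of their counts lay between 21.3 and 57.5 for every pair, so no library was a copy of another. Levels are given as CPM, counts scaled to a common library size with TMM factors,, as mean ± SD with n = 3.

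Genes kept by edgeR's filterByExpr (15764 genes, minimum count 10) were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, glmQLFit with robust estimation and glmQLFTest in one model over the 4 groups, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The contrasts were TAC against sham in each genotype, T497A against wild type after each surgery, the genotype by surgery interaction (the TAC effect in T497A minus that in wild type), and both main effects averaged over the other factor. Fold changes are given as log2 ± a standard error (SE). It was derived from the test as the size of the log2 fold change divided by the square root of the F statistic.

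Gene lists for 33 pathways, cell types and quality signs were written before the data were examined. Of these, 32 were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with the correlation estimated per list and with fry, all adjusted over the lists of a comparison. The lists cover fetal and hypertrophic genes, sarcomere, calcium handling, ion channel, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded, tricarboxylic acid cycle and branched-chain amino acid, glycolysis, extracellular matrix and fibrosis, integrated stress response and one-carbon, unfolded protein and heat shock, immediate early, cytokine, interferon-stimulated, protein kinase C, circadian, cell cycle, ribosomal protein and sex-linked genes. The marker lists cover fibroblasts, endothelium, smooth muscle and pericytes, macrophages, lymphocytes, neutrophils, atrial cardiomyocytes, epicardium, adipocytes, erythrocytes, Schwann cells and nerve, skeletal muscle, and lung and thymus. The last had 1 tested member and was not tested as a list. Counts of list members are given over all genes tested and as adjusted over the list alone.

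A TAC score was computed per library as the mean log2 CPM of the 1769 genes higher after TAC on average minus that of the 1764 genes lower. Its interaction was tested 2-sided by exact permutation of genotype within each surgery (400 arrangements, smallest possible p 0.005), and its difference between single groups by exact permutation of 3 against 3 libraries, which cannot give a p below 0.1.

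The genes named were set by a rule written beforehand. Per comparison these are the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 5, no overlap between the libraries of the groups (not required for the interaction and the averages) and a symbol that is not a predicted-gene name. Where fewer than 5 genes passed, the 5 with the smallest p were named. From each list described, up to 4 members with the smallest p were added, and Prkca, Nppa, Nppb, Myh6, Myh7, Acta1, Ankrd1, Atp2a2, Ppp1r1a, Col1a1, Col3a1 and Postn were always reported. A few genes that the rule names are not reported here. The closest transcripts of genes called between genotypes after sham were found with blastn 2.17.0.

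The alternatives were RLE size factors, no low-count filter, a stricter filter (CPM of at least 1 in at least 3 libraries), DESeq2 1.42.0 and limma-voom. Others were the libraries of the compared groups only, the first surrogate variable from sva 3.50.0 as covariate, and other correlations and tests for the lists. Other genes for the score and leaving out each of the 12 libraries in turn were also set. By its permutation method sva found 3 surrogate variables and by its asymptotic method 0, and only the first was fitted. Leaving out mitochondrial genes before normalization was added after the data had been seen. A covariate for sex was not run, since all 12 libraries had Y-linked transcripts (174 to 252 CPM summed) and at most 16 counts of Xist. The gene tests were tested on simulated counts with 200 changed genes among 15764, drawn from genes with a mean CPM of at least 1. The changes were placed in the wild type TAC libraries alone. At changes of 1.5, 2 and 4 times there, they recovered 41.8%, 76.1% and 100% for TAC against sham in wild type. They recovered 50.7%, 77.6% and 100% for T497A against wild type after TAC and 20.9%, 55.2% and 90.9% for the interaction. For TAC averaged over genotypes they recovered 7.46%, 58.2% and 93.9%. There each change was averaged with an unchanged genotype, so it was smaller than the 1.5, 2 or 4 times named. A score of the changed genes in the simulated counts had an expected interaction of -2.38, found at -2.37. Its permutation test missed that interaction (exact permutation p = 0.09).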

Results

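Transcript levels were measured by RNA sequencing in the left ventricle of wild type mice and of mice with the T497A substitution in Prkca, the gene for protein kinase C alpha, a calcium-dependent kinase of heart muscle. The replaced threonine lies in the kinase's activation loop, a site at which the kinase is phosphorylated. Mice had either a sham operation or TAC, a band around the aortic arch that loads the left ventricle with pressure and leads to hypertrophy and fibrosis, and tissue was taken 5 weeks later. Each of the 4 groups held 3 libraries. Their totals ran from 36862004 counts in wild type sham replicate 3 to 46898344 in T497A sham replicate 3, so depth differed little between groups. The comparisons ask what pressure overload does to the ventricle in each genotype, whether the genotypes differ at rest, and whether the response to TAC depends on the substitution.

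Prkca itself (ENSMUSG00000050965.14, chromosome 11, positions 107933387 to 108343928 of GRCm38) was expressed in every library. Its level was 40.3, 56.5 and 46.6 CPM in the wild type sham libraries, 62.3, 50 and 59.7 in wild type TAC, 38.1, 50.3 and 44.6 in T497A sham and 52.7, 54.4 and 53.8 in T497A TAC. Averaged over genotypes it rose 1.20-fold after TAC (log2 fold change 0.27 ± 0.09 SE, adjusted p = 0.0456 with edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted), and no other comparison called it. After TAC in wild type its log2 fold change was 0.26 ± 0.13 (adjusted p = 0.152), and between genotypes it was -0.11 ± 0.13 after sham and -0.10 ± 0.13 after TAC (adjusted p = 1 and 0.706). A base substitution need not change a gene's count, so these values do not check the genotype labels. In a principal component analysis the first component held 32.1% of the variance. On it the wild type TAC libraries lay at 54.4, 40.2 and 56.8, the T497A TAC libraries at -2.23, 14.9 and -1.12, and the 6 sham libraries between -35.7 and -14.2.

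TAC in wild type hearts was accompanied by a broad change that covered natriuretic peptides, fetal isoforms of contractile proteins, matrix genes and energy metabolism. Nppa, which encodes the natriuretic peptide of the atria and of stressed ventricle, rose from 31.9 ± 15.0 to 827 ± 345 CPM (SD, n = 3), a 25.8-fold increase (log2 fold change 4.69 ± 0.59 SE). The skeletal actin gene Acta1, a fetal isoform, rose 13.1-fold (3.71 ± 0.68), the slow myosin gene Myh7 6.98-fold (2.80 ± 0.66), Nppb 5.12-fold (2.36 ± 0.61) and Ankrd1, a stress-responsive protein of the sarcomere, 3.70-fold (1.89 ± 0.32). The matrix protein gene Postn (periostin) rose 11.3-fold, from 50.9 ± 7.18 to 577 ± 28.4 CPM, and the fibrillar collagen genes Col1a1 and Col3a1 rose 4.23-fold and 3.54-fold. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell 1.74-fold, from 17710 ± 832 to 10150 ± 762 CPM, and the adult myosin gene Myh6 fell 1.53-fold. Ppp1r1a, which encodes inhibitor 1 of protein phosphatase 1, fell 2.50-fold at a low level, from 1.68 ± 0.47 to 0.67 ± 0.19 CPM. The adjusted p of these 11 genes with edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted, ran from 5.49e-05 for Atp2a2 to 0.0229 for Nppb.

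**Figure D1:**
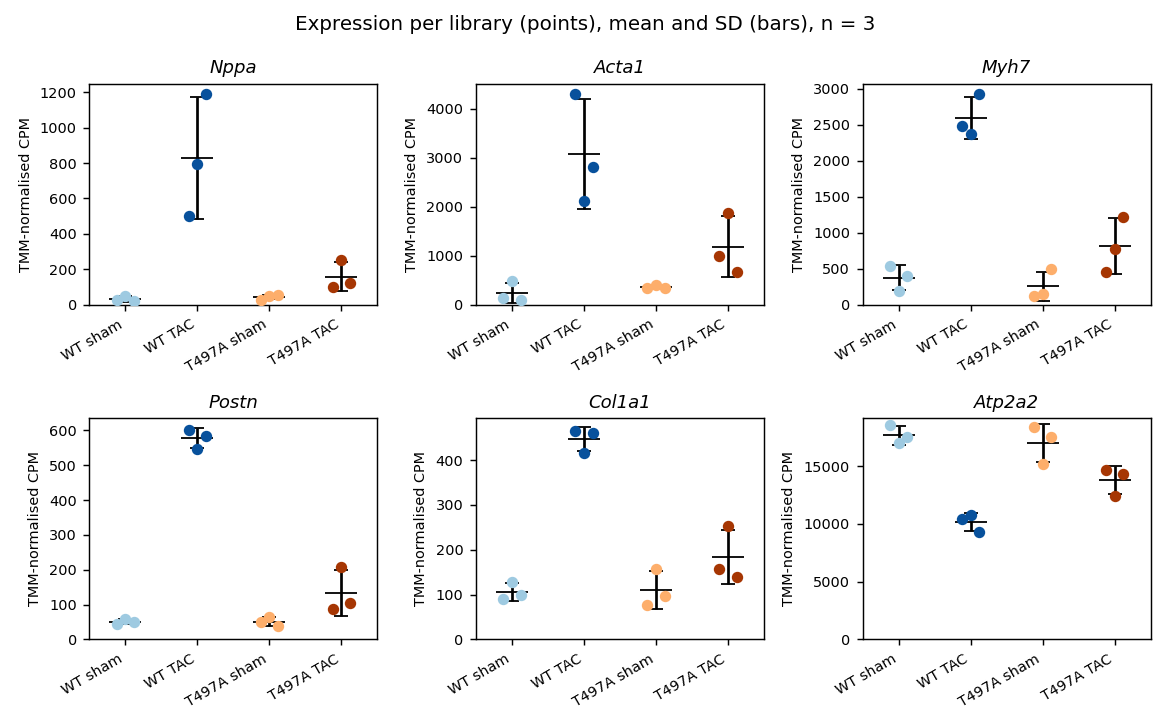
TMM-normalised CPM of 6 genes in each of the 12 libraries, on linear axes from 0; points are libraries, bars the mean and SD of 3. Nppa averaged 827 CPM in wild type TAC and 158 in T497A TAC, Postn 577 and 133, and Atp2a2 10150 and 13780.

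Among the other genes with the largest rises in wild type were the matrix genes Cilp (21.8-fold), Ltbp2 (16.2-fold), Thbs4 (15.9-fold), Col8a2 (14.0-fold) and Comp (12.0-fold), the growth factor gene Fgf6 (13.1-fold) and the endothelin gene Edn3 (11.5-fold). Among the largest falls were those of the water channel gene Aqp4 (12.2-fold), Rab6b (9.89-fold, adjusted p = 0.0466 with edgeR's quasi-likelihood test), the carboxylesterase gene Ces1d (9.82-fold) and Pfkfb1, which sets the level of a glycolytic regulator (8.25-fold). The potassium channel subunit gene Kcnv2, Acsm5, Sbk3, Cenpf and Col6a6 fell 4.56-fold to 5.93-fold. Of the 46 extracellular matrix and fibrosis genes, 45 rose and 46 did when adjusted over the list alone, with a median log2 fold change of 2.09; the oxidase gene Nox4 rose 7.44-fold and Lox, a collagen cross-linking enzyme, 6.31-fold. Of the 14 fetal and hypertrophic genes 13 rose, as did the same number adjusted over the list alone (median 1.93), with Sprr1a 42.7-fold and Uchl1 3.91-fold higher. Both lists passed camera with the preset correlation (adjusted p = 9.4e-30 and 2.5e-10) and not with the estimated one (adjusted p = 0.082 with an estimated correlation for each).

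Genes of mitochondrial energy supply fell together. All 26 genes of the tricarboxylic acid cycle and branched-chain amino acid list fell (26 adjusted over the list alone, median -0.57), led by Ppm1k, the phosphatase that activates branched-chain ketoacid breakdown (2.64-fold). Of 34 fatty acid oxidation genes 26 fell (31 adjusted over the list alone, median -0.65), with Acaa2, the last enzyme of the mitochondrial cycle, 2.27-fold and the acyl-CoA synthetase gene Acsl1 1.69-fold lower. Of 43 nuclear genes of oxidative phosphorylation 40 fell (41 adjusted over the list alone, median -0.40; Sdha, a subunit of complex II, 1.71-fold), and so did all 13 mitochondrially encoded genes (13 adjusted over the list alone, median -0.67; mt-Nd5 1.67-fold). The share of counts from the mitochondrial genome was 26.9% ± 1.94 (SD, n = 3) in wild type sham and 20.1% ± 0.698 in wild type TAC. Adjusted p with the preset correlation was at most 3.2e-09 for these lists; adjusted p = 0.082 with an estimated correlation for the first and second list and 0.12 for the others. Of 21 ion channel genes 15 fell (15 adjusted over the list alone, median -0.69), including Kcnd2 and Kcnip2, pore and accessory subunits of the transient outward potassium current (2.96-fold and 2.13-fold). It was the 1 list whose call held there, with adjusted p = 0.041 with an estimated correlation. Of 22 calcium handling genes 11 fell and 2 rose (11 and 3 adjusted over the list alone, median -0.38, adjusted p = 0.15 with an estimated correlation), including Hrc, Camk2a, Atp2a2 and the release channel gene Ryr2 (1.81-fold).

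Markers of non-muscle cells and of dividing cells also moved in wild type. Of 20 cell cycle genes 14 rose and Cenpf fell (15 and 1 adjusted over the list alone, median 1.34; adjusted p = 0.33 with an estimated correlation), and Ccnb1 and Cdk1 were 7.24-fold and 3.18-fold higher at low levels, 1.81 ± 0.22 and 3.41 ± 0.35 CPM after TAC. Of 18 macrophage markers 11 rose (13 adjusted over the list alone, median 0.89; adjusted p = 0.30 with an estimated correlation), among them the complement gene C1qa (2.03-fold). Of 13 fibroblast markers 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.64; adjusted p = 0.33 with an estimated correlation): the proteoglycan gene Dcn rose 1.56-fold and Scara5, a ferritin receptor gene, fell 3.05-fold. Of 9 erythrocyte markers 4 rose (6 adjusted over the list alone, median 0.88; adjusted p = 0.37 with an estimated correlation); globin genes have near-identical copies, so their counts are uncertain. The list of stress response and one-carbon genes passed the preset test too (7 of 16 rose and 1 fell, the same adjusted over the list alone, median 0.63; Nupr1 5.53-fold, Gdf15 10.7-fold higher). So did those of cytokines (9 of 23 rose, 9 adjusted over the list alone, median 0.57), interferon-stimulated genes (9 of 25 rose, 9 adjusted over the list alone, median 0.64; Irf7 1.92-fold) and immediate early genes (3 of 17 rose, 3 adjusted over the list alone, median 0.74). Adjusted p = 0.082, 0.30, 0.46 and 0.46 with an estimated correlation in that order. Of 45 cytosolic ribosomal protein genes 3 rose (1 adjusted over the list alone, median 0.09; adjusted p = 0.69 with an estimated correlation), with Rpl3 at 0.94 ± 0.15.

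In all, 3936 of 15764 genes were called for TAC against sham in wild type, 1943 higher and 1993 lower, of which 666 and 353 changed at least 2-fold; 5719 had an unadjusted p under 0.05. In 3869 of the 3936 no TAC library overlapped a sham library, as in 42.2% of all tested genes, where chance gives 10%. Of 32 lists 17 were called with the preset correlation, 11 up and 6 down, and 1 with the estimated one.

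TAC in T497A hearts gave smaller changes, and few passed the test for single genes. Among the genes that rose were the lysosomal protease gene Ctss (log2 fold change 0.87 ± 0.15, 1.83-fold), the innate receptor gene Tlr2 (0.87) and Mgp, an inhibitor of calcification (0.74 ± 0.11). The others were Slfn2 (0.68 ± 0.12), the heparan sulfatase gene Sulf1 (0.63 ± 0.09), the matrix gene Ecm2, the interferon gamma receptor gene Ifngr1, Nkd2 (1.15), and Nupr1 (0.94 ± 0.14) and Mthfd2 (1.02) of the stress response list. Among the genes that fell were the phosphorylase kinase gene Phkg1 (2.07-fold), the muscle fructose bisphosphatase gene Fbp2, the fatty acid transporter gene Slc27a1 (1.52-fold), Gpt, the cardiac transcription factor gene Tbx5 and Creg1. Tlr2 and Nkd2 were named after their values were seen. The 18 genes called (10 higher, 8 lower; 1837 with an unadjusted p under 0.05) had an adjusted p between 0.0318 and 0.0497 with edgeR's quasi-likelihood test. All 10 and all 8 were also called in the same direction in wild type, where independent lists would share 1.20 and 1.00. The T497A TAC and sham libraries did not overlap in 15.4% of all tested genes, where chance gives 10%.

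The markers that rose in wild type lay above their sham level in T497A, and those that fell lay below it, without passing the test. Nppa was at 42.7 ± 13.3 CPM after sham and 158 ± 82.9 after TAC (SD, n = 3; log2 fold change 1.89 ± 0.52, adjusted p = 0.226 with edgeR's quasi-likelihood test), and Acta1 at 361 ± 38.9 and 1181 ± 620 (1.71 ± 0.63). Myh7 was at 253 ± 207 after sham and 815 ± 383 (1.69 ± 0.63) and Postn at 50.3 ± 12.9 and 133 ± 65.6 (1.40 ± 0.32, adjusted p = 0.164). Atp2a2 was at 17030 ± 1680 and 13780 ± 1240 (-0.31 ± 0.09). Nppb, Ankrd1, Col1a1 and Col3a1 had log2 fold changes of 0.76 ± 0.58, 0.97 ± 0.31, 0.73 ± 0.30 and 0.56 ± 0.35, Myh6 -0.22 ± 0.14 and Ppp1r1a -1.26 ± 0.35. As lists, the matrix genes had a median of 0.74 (0 of 46 called over all genes, 31 higher adjusted over the list alone), fetal and hypertrophic genes 0.63 (0 of 14, 8 higher adjusted over the list alone) and interferon-stimulated genes 0.56 (0 of 25, 3 higher adjusted over the list alone). Oxidative phosphorylation had a median of -0.22 (0 of 43, 37 lower adjusted over the list alone), fatty acid oxidation -0.29 (1 of 34, 25 lower adjusted over the list alone), the tricarboxylic acid cycle list -0.22 (0 of 26, 20 lower adjusted over the list alone) and mitochondrially encoded genes -0.31 (0 of 13, 12 lower adjusted over the list alone), beside a mitochondrial share of counts of 29.2% ± 1.48 after sham and 25.3% ± 0.77 after TAC.

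With the preset correlation 16 lists were called in T497A, 7 up and 9 down, and with the estimated one 0 (adjusted p = 0.099 to 0.49 with an estimated correlation). The others were the stress response (median 0.32), cytokine (0.36), fibroblast (0.26) and macrophage (0.32) lists, higher, and the sarcomere (-0.11), calcium handling (-0.11), ion channel (-0.19), Schwann cell (-0.68) and skeletal muscle (-2.30) lists, lower. Skeletal muscle transcripts were uneven between libraries: Myh4 was at 10.6, 10.7 and 0.748 CPM after sham and 0.848, 0.0483 and 0.0463 after TAC in T497A, and at 9.56, 5.23 and 0.0581 in wild type sham. With fry 9 lists were called. The count of 18 genes was 297 with DESeq2, 331 without a low-count filter, 8 with a surrogate variable, 0 with limma-voom and 0 when only these 6 libraries were fitted. It was 6, 0 and 0 without T497A sham replicates 1, 2 and 3 and 36, 0 and 7 without T497A TAC replicates 1, 2 and 3.

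**Figure D2:**
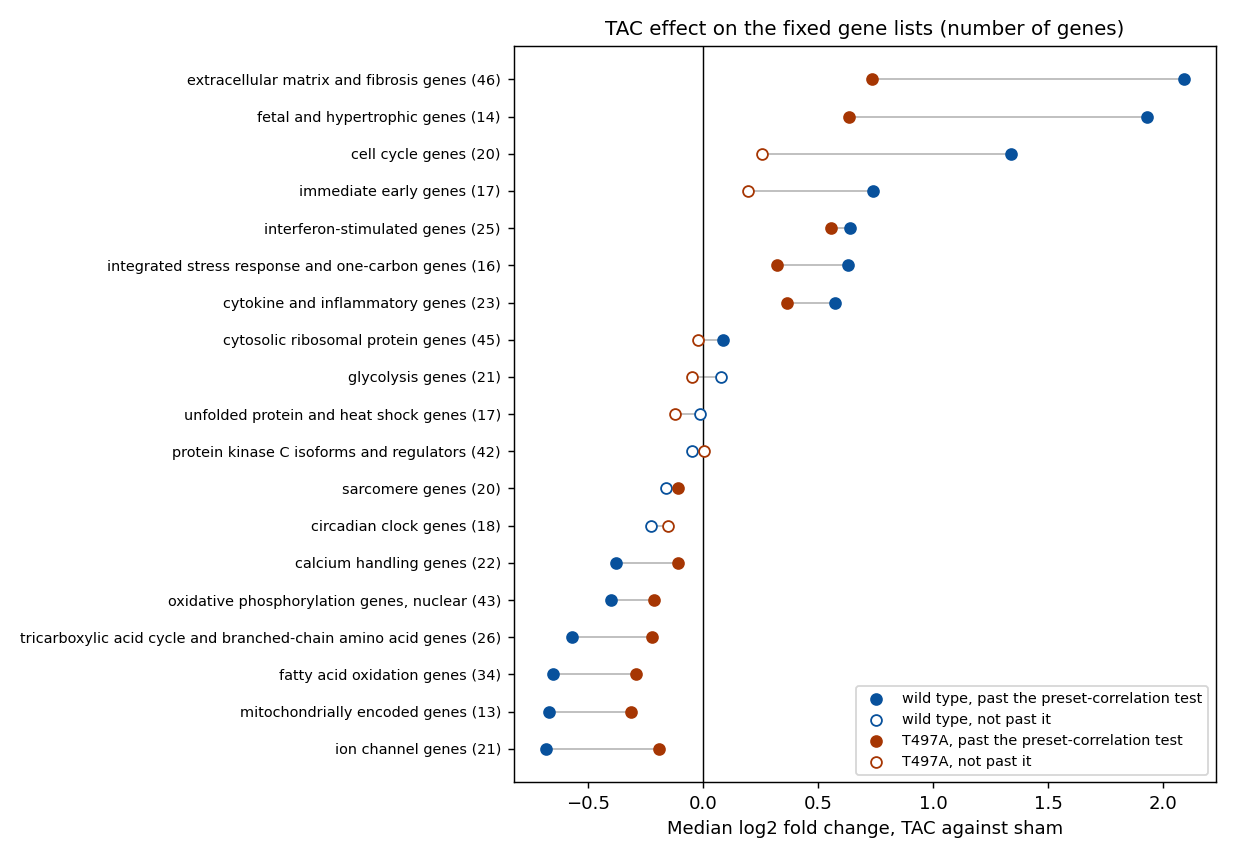
Median log2 fold change after TAC for the fixed gene lists, with the number of tested genes in parentheses; filled points passed camera with a preset correlation. The matrix list lay at 2.09 in wild type and 0.74 in T497A, and the ion channel list at -0.69 and -0.19.

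After sham surgery the genotypes differed in 4 genes, all higher in T497A. Gpr179 (ENSMUSG00000070337.4, chromosome 11, 97332109 to 97352077) encodes a G protein-coupled receptor best known from the retina. It had 1, 1 and 6 counts in the wild type libraries and 123, 143 and 53 in the T497A libraries. Gpr179 thus averaged 0.07 ± 0.09 and 2.73 ± 1.43 CPM (log2 fold change 5.28 ± 0.75, adjusted p = 0.043 with edgeR's quasi-likelihood test). The other genes are annotated as processed pseudogenes. Gm10039 (chromosome 11, 100361716 to 100362126) was 6.44-fold higher (2.69 ± 0.15), at 12.8 against 1.98 CPM (adjusted p = 1.1e-06). Gm7666 (chromosome 15, from 6653923) was 4.50-fold higher (2.17 ± 0.27, adjusted p = 0.0128) and Gm6612 (chromosome 15, from 80952505) 16.2-fold (4.02 ± 0.58, adjusted p = 0.0429). Their sequences match expressed genes at 99.8% (Gm10039, Atp5g1), 99.9% (Gm7666, Phb) and 92.0% (Gm6612, Atp5g1), so their counts are uncertain. H2-Ab1, a class II histocompatibility gene that presents antigen, had the next smallest p and did not pass (2.08-fold, 7.72 ± 0.46 against 16.0 ± 2.30 CPM, adjusted p = 0.130).

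None of the markers of hypertrophy or fibrosis passed between genotypes after sham. Nppa had a log2 fold change of 0.42 ± 0.51, Postn -0.02 ± 0.32, Col1a1 0.06 ± 0.29 and Atp2a2 -0.06 ± 0.09, each with an adjusted p of 1 with edgeR's quasi-likelihood test. Of the lists, the mitochondrially encoded genes (median 0.19), macrophage (0.15), lymphocyte (0.72), adipocyte (0.90) and erythrocyte (0.26) markers were called higher in T497A with the preset correlation. No member of them passed over all genes; adjusted over the list alone 1 macrophage marker, Mpeg1 (0.88 ± 0.22), did. Adjusted p = 0.77 with an estimated correlation for each, and fry called 0 lists. After sham the genotypes did not overlap in 8.21% of all tested genes, where chance gives 10%. The 4 genes (477 of 15764 with an unadjusted p under 0.05) became 14 without a low-count filter, 11 with DESeq2 and 2 with limma-voom or a surrogate variable. Without T497A sham replicate 2 the count was 1 and without replicate 3 it was 2; the 5 called lists became 2 without wild type sham replicate 1, 1 without T497A sham replicate 2 and 3 with mitochondrial genes left out.

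After TAC the genotypes differed widely, and several markers that rose in wild type were lower in T497A. Nppa was 5.23-fold lower in T497A TAC than in wild type TAC (158 ± 82.9 against 827 ± 345 CPM, SD, n = 3; log2 fold change -2.39 ± 0.53, adjusted p = 0.0294 with edgeR's quasi-likelihood test), Postn 4.34-fold (-2.12 ± 0.33, adjusted p = 0.00648) and Col1a1 2.44-fold (-1.29 ± 0.30, adjusted p = 0.0316). Atp2a2 was 1.36-fold higher (0.44 ± 0.09, adjusted p = 0.0115). The others did not pass: Nppb (-1.26 ± 0.59), Myh7 (-1.67 ± 0.63), Acta1 (-1.38 ± 0.63), Ankrd1 (-0.99 ± 0.31), Col3a1 (-1.14 ± 0.36), Myh6 (0.20 ± 0.14) and Ppp1r1a (-0.30 ± 0.36). Their adjusted p ran from 0.0898 to 0.668.

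Among called genes of at least 5 CPM on average whose groups did not overlap, predicted genes aside, the largest difference downward after TAC was in Dio2, the enzyme that activates thyroid hormone (6.03-fold, 3.98 ± 0.33 against 24.0 ± 7.16 CPM). Other large differences were those of Nmrk2, a kinase of nicotinamide riboside (5.10-fold), Col8a2 (4.53-fold), Thbs4 (4.38-fold), Fgf6 (4.36-fold), Cilp (4.15-fold) and Col12a1 (3.86-fold). Upward, among the same genes, the largest was in Ces1d (5.17-fold, 57.4 ± 9.71 against 11.1 ± 4.48 CPM), followed by Cenpf (3.76-fold), Myorg (3.55-fold), Col6a6 (3.35-fold), the neurotrophic factor receptor gene Gfra1 (2.79-fold), Akr1e1 (2.77-fold), Cep128 (2.64-fold), Enpp2, which makes lysophosphatidic acid (2.59-fold), Aldh1l2 (2.50-fold) and Klhl33 (2.46-fold). Of the 46 matrix genes 29 were lower in T497A (42 adjusted over the list alone, median -1.27; Lox 3.58-fold), and of the 14 fetal and hypertrophic genes 8 (11 adjusted over the list alone, median -1.14; Sprr1a 12.8-fold, Uchl1 2.68-fold). Of the 20 cell cycle genes 4 were lower and Cenpf higher (8 and 1 adjusted over the list alone, median -0.94). Adjusted p = 0.11, 0.11 and 0.36 with an estimated correlation for these lists.

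Genes of energy supply were higher in T497A after TAC: 17 of 26 in the tricarboxylic acid cycle list (20 adjusted over the list alone, median 0.28; Ppm1k 1.82-fold) and 16 of 34 in fatty acid oxidation (22 adjusted over the list alone, median 0.37; Acaa2 1.58-fold). So were 14 of 43 in oxidative phosphorylation (24 adjusted over the list alone, median 0.17) and 9 of 13 mitochondrially encoded (13 adjusted over the list alone, median 0.52; mt-Nd5 1.42-fold). The mitochondrial share of counts was 25.3% ± 0.77 (SD, n = 3) in T497A TAC and 20.1% ± 0.698 in wild type TAC. Adjusted p = 0.16, 0.11, 0.30 and 0.11 with an estimated correlation in that order. Of the 21 ion channel genes 7 were higher (11 adjusted over the list alone, median 0.35, adjusted p = 0.11 with an estimated correlation), with Kcnd2 2.34-fold and Kcnip2 1.69-fold. The preset test also called the stress response list lower (median -0.29; Nupr1 2.44-fold, Gdf15 4.85-fold lower; adjusted p = 0.11 with an estimated correlation), the immediate early list (-0.51, 0 of 17 called; adjusted p = 0.65 with an estimated correlation) and the ribosomal protein list (-0.09, 2 of 45 lower; adjusted p = 0.65 with an estimated correlation). Of 22 calcium handling genes 6 were higher, among them Hrc (log2 fold change 0.58) and Ryr2 (0.56), without a call for the list.

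Between genotypes after TAC 1371 genes were called, 731 higher and 640 lower in T497A (102 and 152 of them at least 2-fold; 3782 with an unadjusted p under 0.05), and 11 of 32 lists with the preset correlation, 5 higher and 6 lower, and 0 with the estimated one. The groups did not overlap in 1361 of the 1371 and in 28% of all tested genes, where chance gives 10%. The count fell to 876 without wild type TAC replicate 1, to 463 without replicate 3, to 653 without T497A TAC replicate 1 and to 592 without replicate 3. This comparison shares its wild type TAC libraries with that of TAC in wild type, so the lists of genes from both are not independent.

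Whether the response to TAC itself differed between genotypes was tested with the interaction, the TAC effect in T497A minus that in wild type. It was called in 248 genes (141 positive, 107 negative; 2647 with an unadjusted p under 0.05), and most named genes had a smaller response in T497A. Dio2 went from 2.45 ± 0.74 to 24.0 ± 7.16 CPM in wild type and from 2.20 ± 0.84 to 3.98 ± 0.33 in T497A (SD, n = 3; interaction -2.43 ± 0.43, adjusted p = 0.0234 with edgeR's quasi-likelihood test). Col6a6, a collagen chain, went from 17.2 ± 3.13 to 3.76 ± 0.82 CPM and from 16.3 ± 0.54 to 12.6 ± 0.76 (1.82 ± 0.22, adjusted p = 0.00467). Other positive interactions were those of Ces1d (2.29), Aqp4 (2.22), Aldh1l2 (1.68), Sorcs2 (1.59), Gfra1 (1.43), Dcaf12l1 (1.34), Pla2g5 (1.32) and Pdp2, a phosphatase that activates pyruvate dehydrogenase (1.27). Other negative ones were those of Edn3 (-2.28), the microfibril gene Mfap5 (-2.05), the steroid transport gene Star (-2.02), Pamr1 (-1.79), Lox (-1.72), Uchl1 (-1.72), the microtubule protein gene Map6 (-1.71), Serpina3n (-1.68) and Dbn1 (-1.51).

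None of the markers fixed beforehand passed the interaction test as single genes: Nppa had -2.80 ± 0.73 (adjusted p = 0.0989 with edgeR's quasi-likelihood test), Postn -2.10 ± 0.45 (0.0606), Atp2a2 0.50 ± 0.13 (0.0734), Acta1 -2 ± 0.88, Nppb -1.60 ± 0.82, Col1a1 -1.35 ± 0.42, Col3a1 -1.26 ± 0.50, Myh7 -1.12 ± 0.87, Ankrd1 -0.92 ± 0.44, Myh6 0.39 ± 0.20 and Ppp1r1a 0.06 ± 0.49. Of the matrix genes 8 of 46 had a called negative interaction (30 adjusted over the list alone, median -1.32), and of the fetal and hypertrophic genes Uchl1 alone (7 of 14 adjusted over the list alone, median -1.28). Positive interactions were called in 6 of 26 genes of the tricarboxylic acid cycle list (19 adjusted over the list alone, median 0.32), 5 of 34 of fatty acid oxidation (14 adjusted over the list alone, median 0.34), 2 of 21 ion channel genes (10 adjusted over the list alone, median 0.48) and 2 of 22 calcium handling genes (4 adjusted over the list alone, median 0.16). The preset test called 15 lists, 6 positive and 9 negative. Adjusted p = 0.19, 0.19, 0.21, 0.23, 0.084 and 0.37 with an estimated correlation for these lists in that order, and no list passed there, while 7 did with fry.

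The TAC score set the mean of 1769 genes higher after TAC on average against that of 1764 genes lower. TAC raised it by 1.65 in wild type, from -2.22 ± 0.11 to -0.57 ± 0.15 (SD, n = 3), and by 0.71 in T497A, from -2.12 ± 0.13 to -1.42 ± 0.19, which is 42.8% of the wild type effect. The interaction was -0.95 ± 0.17 SE (exact permutation of genotype within surgery, 2-sided p = 0.025, smallest possible 0.005). The mean of the matrix genes gave 42.0% and an interaction of -1.36 ± 0.32, which was not under the threshold (exact permutation p = 0.05). That of the fetal and hypertrophic genes gave 36.6% and -1.40 ± 0.31 (exact permutation p = 0.045). With genes picked in T497A the score's interaction was -1.34 and did not pass (exact permutation p = 0.065). For the 2 fixed lists the difference between sham and TAC within each genotype, and between genotypes after TAC, reached the smallest p that 3 against 3 libraries allow (exact permutation p = 0.1). The score's difference between genotypes after TAC reached it too (exact permutation p = 0.1). An interaction p below 0.1, for the score or a list, thus also rested on the order of the sham libraries. The permutation exchanges genotype after both surgeries. Its null is therefore no genotype difference after either, not an equal TAC effect alone. The score's genes were picked for their TAC effect in these libraries, so it does not test sham against TAC; between genotypes after sham its exact permutation p was 0.5.

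**Figure D3:**
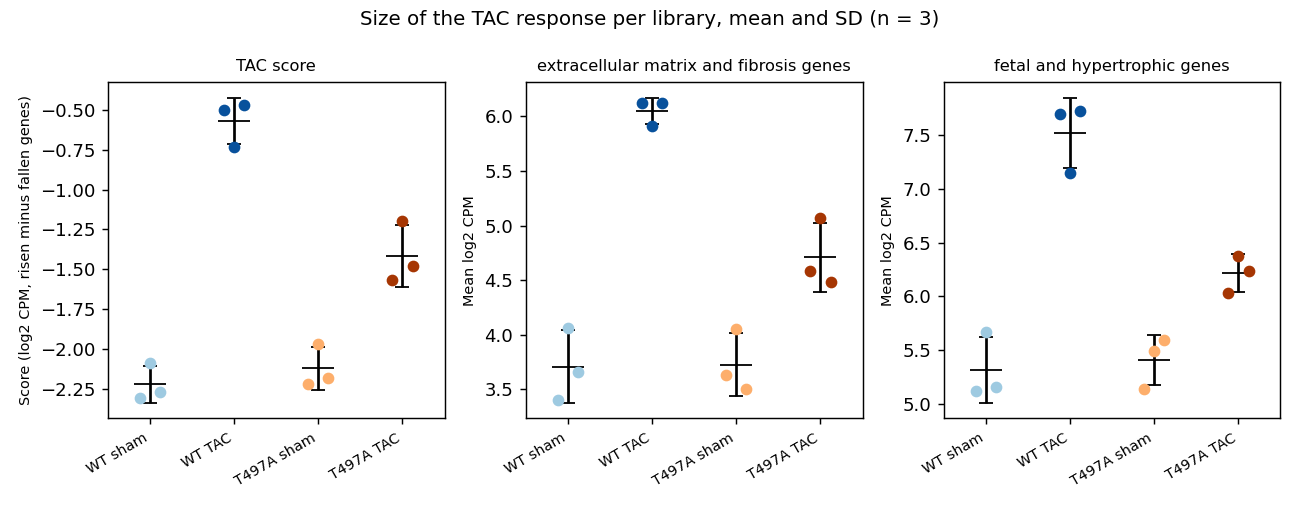
TAC score and mean log2 CPM of the matrix and the fetal lists in each of the 12 libraries; points are libraries, bars the mean and SD of 3. The T497A TAC mean of -1.42 lies between the sham means of -2.22 and -2.12 and the wild type TAC mean of -0.57.

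The genes higher after TAC on average had a mean log2 fold change of 0.47 in T497A and 1.02 in wild type (46.3%), and the genes lower on average -0.28 and -0.69 (40.1%). These genes were picked in the same libraries, so that both means lie away from 0 follows from the choice. Over all genes the TAC effects of the genotypes correlated with Pearson's r = 0.421 and Spearman's rho = 0.474, across genes, which are not independent replicates; the comparisons share no libraries. Without T497A TAC replicate 2 Pearson's r was 0.271, and it was lower than with all libraries whichever library was left out (at most 0.377). These refits repeated the low-count filter and tested 16163 to 16260 genes. The lower values thus mix a change of the genes tested with the loss of a library. The 248 interaction calls were 898 without a low-count filter and 859 with DESeq2. Leaving out a library gave 77, 40, 133, 44, 91, 77, 77 and 67 without wild type sham replicates 1 and 3, wild type TAC replicates 1 and 3, T497A sham replicates 2 and 3 and T497A TAC replicates 1 and 3, and 517 without T497A TAC replicate 2.

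Averaged over genotypes, Cilp rose 9.92-fold after TAC, Nppa 9.78-fold, Ltbp2 8.21-fold, Thbs4 7.48-fold, Fmn1 6.59-fold (2.61 to 10.0 CPM in wild type, 2.72 to 30.5 in T497A), Acta1 6.55-fold, Postn 5.48-fold, Comp 5.46-fold, Nlrc3 5.33-fold and Edn3 5.21-fold. Aqp4 fell 5.63-fold, Ces1d 4.44-fold, Pfkfb1 4.36-fold, Cacng6 3.71-fold, Sbk3 3.27-fold, Kcnv2 3.05-fold, Acsm5 3.01-fold, Cenpf 2.86-fold and Efemp1 2.81-fold (adjusted p at most 0.0279 with edgeR's quasi-likelihood test). Of the interferon-stimulated genes 14 of 25 rose (18 adjusted over the list alone, median 0.64; adjusted p = 0.35 with an estimated correlation), and of the lymphocyte markers 2 of 12 (2 adjusted over the list alone, median 0.59; adjusted p = 0.36 with an estimated correlation). The average called 3533 genes, 1769 higher and 1764 lower (5470 with an unadjusted p under 0.05), and 18 lists, of which 1 held with an estimated correlation, ion channel genes (12 of 21 fell, 12 adjusted over the list alone, adjusted p = 0.044).

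Averaged over surgeries, 134 genes differed between genotypes, 79 higher and 55 lower in T497A (2168 with an unadjusted p under 0.05). Higher in T497A were Myorg (2.34-fold), Ces1d (2.34-fold), Aqp4 (2.20-fold), Kcnv2 (2.19-fold), Efemp1 (1.83-fold), Enpp2 (1.79-fold), Col6a6 (1.78-fold), Gfra1 (1.70-fold) and Amy1 (1.63-fold), whose counts are uncertain since it belongs to a family of near-identical amylase genes. Lower were Dio2 (2.60-fold), Lox (1.97-fold), Mfap5 (1.86-fold), Star (1.83-fold), Col16a1 (1.68-fold), Epn3 (1.67-fold), Cyb561 (1.58-fold), Pamr1 (1.57-fold), Enpp1 (1.54-fold) and Map6 (1.49-fold), with adjusted p at most 0.0484 with edgeR's quasi-likelihood test. Ces1d, Aqp4, Enpp2, Col6a6, Gfra1, Dio2, Lox, Mfap5, Star, Col16a1, Pamr1, Enpp1 and Map6 also had called interactions, so their average does not describe both surgeries. Map6 was at 4.14 CPM in T497A and 3.42 in wild type after sham and at 3.89 and 10.5 after TAC, and Mfap5, Star and Pamr1 were likewise not lower in T497A after sham. Epn3, an endocytic adaptor gene on chromosome 11, was at 11.8 against 19.1 CPM after sham and 13.4 against 23.1 after TAC. The preset test called 10 lists and the estimated correlation 0, among them matrix genes (4 of 46 lower, 28 adjusted over the list alone, median -0.58; adjusted p = 0.14 with an estimated correlation). The 134 genes became 562 without a low-count filter and 563 with DESeq2. Without wild type sham replicates 1, 2 and 3, wild type TAC replicate 3, T497A sham replicates 1 and 3 and T497A TAC replicates 1, 2 and 3 they became 80, 20, 81, 40, 58, 38, 85, 353 and 51.

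**Figure D4:**
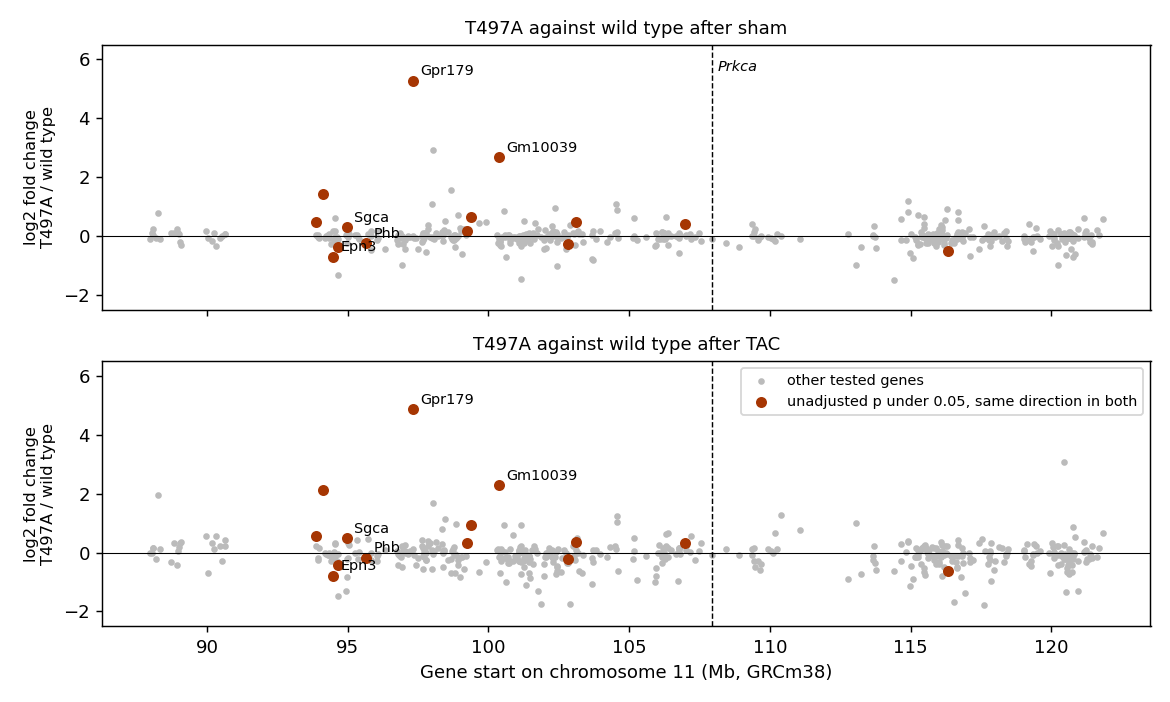
Log2 fold change of T497A against wild type after each surgery for the tested genes around Prkca (dashed line) on chromosome 11, by gene start in Mb of GRCm38. The 14 larger points, among them Gpr179, Gm10039, Epn3, Sgca and Phb, had an unadjusted p under 0.05 in the same direction after both surgeries and lie between 93.9 and 116.3 Mb.

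The genotype differences after sham and after TAC were uncorrelated across genes (Pearson's r = 0.000243, Spearman's rho = -0.07; genes are not independent replicates). All 4 genes called after sham were also called in the same direction after TAC, where independent lists would share 0.19. Gpr179 was at 0.07 ± 0.04 CPM in wild type TAC and 2.05 ± 1.00 in T497A TAC (log2 fold change 4.86 ± 0.74, adjusted p = 0.00279 with edgeR's quasi-likelihood test), and Gm10039 at 2.14 and 10.5 CPM.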

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

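The tests of scaling, of 1 factor for the whole response and of the fibroblast share were chosen only after the result was seen; the tests on other splits of the libraries were set beforehand.

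The TAC effect differed between the genotypes by the interaction test in 248 genes. The TAC score (interaction -0.947) and the mean of the fetal and hypertrophic genes (-1.40) passed the permutation of genotype within surgery. The null of that permutation is no genotype difference after either surgery, and passing it also rested on the order of the sham libraries. A total of 100 splits of the libraries into genotypes within each surgery was run, the real one and others drawn at random. Of these, 4 gave as many genes, the real one included, and the highest other gave 500. That share lies narrowly under 0.05 and splits not drawn could move it, so chance is not firmly excluded. Of the 9 other splits that kept the TAC hearts divided by genotype, 3 gave as many. The highest count among splits that did not keep them so was 4. The structure thus rests on the TAC hearts, while the size of the count also depends on the sham hearts. Measured against 1 factor for all genes, 5 lists departed by camera with the preset correlation and 0 with the estimated one. The 5 were interferon-stimulated (median 0.30), cell cycle (-0.31), ribosomal protein (-0.08), oxidative phosphorylation (-0.05) and skeletal muscle genes (-2.30). Skeletal muscle transcripts were uneven within groups, so the departure of that list cannot be told from this unevenness. Myh4 was at 1.23, 15.6 and 0.186 CPM in wild type TAC and 10.6, 10.7 and 0.748 in T497A sham. Interferon-stimulated genes had a mean TAC effect in T497A at 105% of that in wild type.

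Against a wrong scaling of the libraries, the genes that fell after TAC on average had a mean interaction of 0.417 and those that rose of -0.546, while a scaling error moves both the same way. On a smaller rise in the share of fibroblasts, 11 of 12 fibroblast markers outside the matrix list had an interaction above that list's median (medians -0.317 and -1.32). Scara5 had a called interaction in the other direction (0.94). These markers rose little in wild type (median 0.493, and 0.223 in T497A), so losing all of that rise would still leave them above the matrix median. The count of 11 therefore does not decide the question. It shows only that the share, as these markers measure it, changed too little to make up the matrix interaction alone. The mean TAC effect in T497A was 41.9% of wild type for the whole fibroblast list and 43.4% for the matrix list. A smaller share as a part of the cause, or fewer activated fibroblasts, stays open. With 1 factor for the whole response, T497A at 43.8% of wild type, 0 genes departed from the factor by edgeR's quasi-likelihood test, where 248 departed from an equal response (747 had an unadjusted p under 0.05, 4.74% of genes, and no other tool was run). A response that is smaller in most genes is consistent with a weaker effect of pressure load in T497A hearts and with a milder constriction in these mice alike; load was not measured here, and both stay open.

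Other values were picked out by the same interaction test, as list medians or gene log2 values. The 15 lists were called with the preset correlation, and 0 of them with the estimated one. The lists with a negative median were fetal and hypertrophic genes (-1.28), extracellular matrix (-1.32), stress response and one-carbon (-0.27), immediate early (-0.60), cell cycle (-1.05) and ribosomal protein genes (-0.13), and macrophage (-0.41), erythrocyte (-0.605) and skeletal muscle markers (-2.30). Transcripts of the skeletal muscle list were uneven between the libraries of a group. The lists with a positive median were calcium handling (0.16), ion channel (0.48), fatty acid oxidation (0.34), oxidative phosphorylation (0.145), mitochondrially encoded (0.31) and tricarboxylic acid cycle genes (0.32). Genes with a positive interaction included Ces1d (2.29), Aqp4 (2.22), Col6a6 (1.82), Aldh1l2 (1.68), Sorcs2 (1.59), Gfra1 (1.43), Dcaf12l1 (1.34), Pla2g5 (1.32) and Pdp2 (1.27). Those with a negative one included Dio2 (-2.43), Edn3 (-2.28), Mfap5 (-2.05), Star (-2.02), Pamr1 (-1.79), Lox (-1.72), Uchl1 (-1.72), Map6 (-1.71), Serpina3n (-1.68) and Dbn1 (-1.51).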

How the results depend on the processing

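Leaving out mitochondrial genes before normalization was chosen only after the data had been seen; the other alternatives were set beforehand. No paired analysis was possible because the labels pair no libraries. Over the alternatives, the named genes kept their direction and side of the threshold in 3649 of 4233 refits, were weaker in 549, stronger in 26 and reversed in 9, and the called lists kept theirs in 732 of 884. With RLE size factors 272 of 273 named genes kept theirs, and with the stricter low-count filter 272 of 272. The genes called for TAC against sham in wild type, for its average over genotypes and for T497A against wild type after TAC stayed within 1.5 times under the alternatives tried, except the last when single libraries were left out. Small counts of called genes moved most. For TAC in T497A, T497A against wild type after sham, the interaction and the genotype average, the counts were 331, 14, 898 and 562 without a low-count filter and 297, 11, 859 and 563 with DESeq2; the cause was not tested. For TAC in T497A limma-voom gave 0 (1899 with an unadjusted p under 0.05), the libraries of the compared groups alone 0 (1522) and a surrogate variable 8, and for T497A against wild type after sham limma-voom and the surrogate variable gave 2 each; the cause was not tested.

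With the correlation estimated per list the called lists were 1 for TAC in wild type, 0 in T497A, 0 and 0 between genotypes after sham and after TAC, 0 for the interaction, 1 for the TAC average and 0 for the genotype average; the test allows for the correlation of each list's genes, which the preset value sets low. With fry 9 lists were called for TAC in T497A, 0 between genotypes after sham and 7 for the interaction, and leaving out mitochondrial genes left 3 after sham, where the mitochondrially encoded list is itself removed. The TAC score interaction was -1.13 (exact permutation p = 0.01) with genes picked in wild type, a choice that by itself inflates the wild type effect, and -1.34 (p = 0.065) with genes picked in T497A, where few genes were called; it was -0.946 (p = 0.02) with mitochondrial genes left out.

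Leaving out 1 library at a time, with the spread pooled over groups, gave 2766 to 3483 genes for TAC in wild type, 0 to 36 in T497A, 1 to 5 between genotypes after sham and 463 to 1455 after TAC, 40 to 517 for the interaction, 2779 to 3617 for the TAC average and 20 to 353 for the genotype average. The called lists ran in that order from 16 to 18, 15 to 20, 1 to 7, 12 to 14, 12 to 16, 16 to 20 and 9 to 14. The score's interaction ran from -1.05 to -0.871, and the correlation of TAC effects between genotypes, 0.421 with all libraries, from 0.271 to 0.377. For that correlation and for the gene counts the low-count filter was repeated, so more genes were tested (16163 to 16260). The lowest count between genotypes after TAC came without wild type TAC replicate 3, and the highest for the interaction and the genotype average without T497A TAC replicate 2. Signs reversed for values near 0 that no test called. The interaction of Ppp1r1a ran from -0.191 to 0.38, the lowest without wild type sham replicate 1, with -0.0842, -0.00773, -0.145 and -0.0199 without wild type TAC replicates 1 and 2, T497A sham replicate 1 and T497A TAC replicate 3. The interaction of Prkca ran from -0.126 to 0.123, the lowest without wild type sham replicate 2, with -0.0754 and -0.0852 without wild type TAC replicate 2 and T497A sham replicate 1, and its difference after sham from -0.222 to 0.0272, the highest without wild type sham replicate 2; the cause was not tested. On simulated counts the interaction test found 20.9% of 1.5-fold and 55.2% of 2-fold changes, so small differences in response are missed at this depth and group size.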

Other observations

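All tests of the segment around Prkca and of parent genes in this part were made only after the result was seen. So was the choice of genes of class II antigen presentation. The splits of the libraries were set beforehand.

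Isoforms and regulators of protein kinase C moved in both directions after TAC in wild type (8 of 42 lower and 3 higher, the same adjusted over the list alone, median -0.05; adjusted p = 0.42, and adjusted p = 0.67 with an estimated correlation). Prkcd, the delta isoform, rose 1.88-fold (log2 fold change 0.91 ± 0.18, adjusted p = 0.00241 with edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted) and Prkcq, the theta isoform, fell 1.94-fold (-0.95 ± 0.22, adjusted p = 0.00654). Adra1b, an adrenergic receptor upstream of the kinase, fell 1.93-fold and the transcription factor gene Mef2a 1.47-fold. Between genotypes after TAC Adra1b was 1.64-fold, Mef2a 1.31-fold and the phosphatase gene Phlpp1 1.26-fold higher in T497A, and Nfatc2 1.30-fold lower (adjusted p from 0.00928 to 0.0349). Genes of class II antigen presentation were also looked at. Cd74 was at 31.6 CPM in wild type sham, 65.2 in wild type TAC, 63.4 in T497A sham and 85.9 in T497A TAC. It did not pass between genotypes after sham (adjusted p = 0.941 with edgeR's quasi-likelihood test). H2-Aa was at 13.9, 25.1, 26.5 and 36.5 CPM and H2-Eb1 at 9.68, 23.6, 22.2 and 28.8. Their regulator Ciita was at 1.33 CPM in wild type sham, 1.22 in wild type TAC, 1.40 in T497A sham and 2.65 in T497A TAC, and was called higher in T497A after TAC (adjusted p = 0.0208). No list of these genes was fixed or tested as a set, and macrophage and lymphocyte markers were also called higher in T497A after sham with the preset correlation (medians 0.15 and 0.72; adjusted p = 0.77 with an estimated correlation).

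Other lists did not pass the preset test for TAC in wild type. Sarcomere genes had a median of -0.16 (1 of 20 higher, 6 lower, 3 and 7 adjusted over the list alone; adjusted p = 0.71 with an estimated correlation), with Tnni3, the cardiac inhibitory troponin, 1.55-fold lower and Csrp3, a muscle LIM protein gene, 1.43-fold higher. Glycolysis genes had a median of 0.08 and a mean of -0.05, which differ in sign (5 of 21 higher, 7 lower, 8 and 7 adjusted over the list alone; adjusted p = 0.96 with an estimated correlation), with the glucose transporter gene Slc2a4 1.66-fold lower and Hk1 1.39-fold higher. Unfolded protein and heat shock genes had a median of -0.02, against an upward test (2 of 17 higher and 2 lower, the same adjusted over the list alone; adjusted p = 0.96 with an estimated correlation), with Hspb1 1.65-fold higher and Dnajb9 1.43-fold lower. Medians were -0.23 for circadian genes (0 of 18), 0.08 for endothelial markers (1 of 15, Esam 1.31-fold higher), -0.135 for smooth muscle and pericyte markers (1 higher and 2 lower of 13, Abcc9 2.05-fold lower), 0.78 for lymphocyte (0 of 12) and 0.91 for neutrophil markers (0 of 4). They were 0.09 for atrial markers (1 of 6, Dkk3 2.27-fold higher), 1.79 for epicardial markers (1 of 3, Igfbp6 higher at log2 1.81 ± 0.38), 0.325 for adipocyte markers (0 of 7) and -1.02 for Schwann cell and nerve markers (3 of 7 lower, 4 adjusted over the list alone). Adjusted p = 0.30 to 0.87 with an estimated correlation for these. Sex-linked genes had a median of -0.30 (3 of 5 lower, Uty 1.38-fold; adjusted p = 0.086). Of the lung and thymus markers Sftpb alone was tested (-0.88 ± 0.78, adjusted p = 0.452). Skeletal muscle markers had a median of 0.19, against a downward test (0 of 8), and varied between libraries: Myh4, a fast myosin of skeletal muscle, was at 9.56, 5.23 and 0.0581 CPM in wild type sham, 1.23, 15.6 and 0.186 in wild type TAC, 10.6, 10.7 and 0.748 in T497A sham and 0.848, 0.0483 and 0.0463 in T497A TAC.

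Genotype differences that sham and TAC hearts shared were more frequent within 20 Mb of Prkca than elsewhere. Of 480 tested genes there, 14 (2.92%) had an unadjusted p under 0.05 in the same direction after both surgeries, against 54 of 15271 elsewhere (0.354%; Fisher exact p = 1.3e-08, with genes not independent). Of the 14, 9 started between 90 and 100 Mb, where 7.32% of 123 genes did so, and Rnf157 alone lay beyond Prkca. Most shared genes lay elsewhere, and small groups had higher shares, 3 of 33 genes of the mitochondrial genome (9.09%) and 1 of 13 in a bin of chromosome 3 (7.69%). Of 15764 tested genes, 477 after sham and 3782 after TAC had an unadjusted p under 0.05. Independent lists of these sizes also share genes by chance, so the 54 elsewhere need not be real differences.

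With Gpr179 and Gm10039, called after sham, left out, standardised differences correlated between surgeries at Pearson's r = 0.13 in the window (478 genes, Spearman's rho = 0.067), and none of 23 other blocks of as many genes reached that (highest 0.064). The correlation rested on few genes: it was 0.027 with the shared genes left out as well, such as Epn3, Sgca and Mrpl27, and 1 of 24 other blocks treated alike was as high (0.055). For the called pseudogenes, 3 of 3 had their closest named gene in the window: Atp5g1 for Gm10039 and Gm6612, and Phb for Gm7666. Gm6612 matched at 92.0% only. Atp5g1 itself differed little between genotypes (log2 fold change -0.075 ± 0.09 after sham and -0.036 ± 0.09 after TAC). Phb lay lower in T497A without passing (-0.24 ± 0.06 and -0.17 ± 0.06). A segment of another strain origin linked to the T497A allele, with reads of genes in it counted for their copies, could give these values. Gm10039 itself lies in the window, at 100.4 Mb. How the T497A line was made was not known here. Sequence variants were not examined here, and an effect of the substitution itself on these genes stays open.

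Between the groups of 1 comparison the 10 splits of 6 libraries are too few for a share under 0.05. The real split called 3936 genes for TAC in wild type (highest other 0), 18 for TAC in T497A (highest other 1), 4 between genotypes after sham (3) and 1371 after TAC (7), and in each comparison 1 split, the real one, gave as many. For TAC averaged over genotypes 1 of 100 splits, the real one, gave as many as the real 3533, a share under 0.05. The highest other split gave 3296, near the real count. Splits not drawn could move the share, so chance is not firmly excluded. For the genotype average 8 of 100 gave as many as the real 134 (highest other 1003), so chance cannot be excluded; the 7 others kept the TAC hearts divided by genotype, a structure of the samples, and the highest count among splits that did not was 14.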
